A study of Cucumis sativus with 4 samples.

How the data were processed

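Total RNA from cucumber (Cucumis sativus) fruits at anthesis was sequenced in 4 libraries, 2 from plants carrying an RNA interference construct against CsCRC and 2 from the wild type. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. CsCRC is the cucumber CRABS CLAW gene, a member of the YABBY family of plant transcription factors. HISAT2, a read aligner, and DESeq2, a test for read counts, are named in the submitters' processing notes. Versions, the read counter and the genome build are not given in the sources used here; the gene IDs begin with CsaV3.

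The data are a single deposited table of the authors' own comparison, with 1 line per gene and no column for a library. The deposited mean was taken as a signal value, the mean over all libraries of read counts divided by size factors. Its header, baseMean, is that of a DESeq2 results table and does not itself state this. The deposited log2 fold change and its standard error are on the log2 scale and were not shrunken. The deposited Wald score equalled the fold change divided by its error, with a largest gap of 2.2e-07. The authors' p-value is two-sided, and the authors' adjusted p matched a Benjamini-Hochberg adjustment over the genes that carry one, with a largest relative gap of 0.344%. The adjustment covered 18461 genes, and the smallest mean among them was 4.6.

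The table does not say which genotype is the numerator of the fold change. The 2 genotypes are therefore called numerator and denominator here, and no gene is said to be higher in RNAi or in wild-type fruit. None of the IDs (0 matches) was found in the gene table used for names. The 32 gene lists and the CsCRC transcript, both fixed before the data were examined through gene descriptions, were therefore not analysed here. The same holds for the planned lists of markers of pollen, ovule, phloem and stress. The rule for named genes called for the 10 largest rises and falls that had a description, with at most 4 genes per list. It gave no gene, so the 2 IDs with the smallest adjusted p in each direction are named instead, a choice made after their values were seen.

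Because the deposited mean is a sum of whole reads, each divided by 4 times its library's size factor, the reads behind it could be recovered. Genes with a single read fell on 4 values, 1 for each library, and the sign of their fold change gave the side of the comparison that the library is on. The size factors were fitted from these and other genes of few reads, and all 2610 of the 2610 genes searched had a single whole-number solution. For other genes with a mean of at most 2000, sets of 4 whole numbers that gave the deposited mean to its last digit were listed. The search was limited to sets whose 2 sides lay near the levels that the deposited fold change implies. The band was 4% of the smaller side, and wider for genes of few reads. A set was kept when its fitted fold change, under the dispersion that the deposited error implies, was the only one to match the deposited value. The largest gap among the sets kept was 1.7e-06, but a set was kept only if its gap lay under a preset limit. Reads were recovered for 17661 of 20868 genes with a mean above 0 (84.6%), and for 99.5% of the genes searched. Only the mean was matched for the 2610 genes of few reads, and for 3 other genes in which 1 side held no reads. In simulated tables, 99.9% of 972 genes came back with the right reads and 0 with wrong ones. Among 1000 decoys, real genes whose mean had been moved by a small random amount, 2 still gave a solution. Neither the simulation nor the decoys covered the genes of few reads. Recovered libraries are known by side and depth only: they were not matched to the labelled replicates.

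The deposited comparison is the main result, as planned for a table without values per library. The count test planned for a table of counts (edgeR) was not run, and recovered reads were tested with limma alone. As alternatives chosen after seeing the data, limma voom (limma 3.58.1, R 4.3.3) was run on the recovered reads of 15254 genes that carry an adjusted p, with library sizes in proportion to the size factors. It was repeated without each library in turn and for the other 2 of the 3 ways to split 4 libraries into pairs. On reads simulated for these 15254 genes, limma called 81 of 100 genes changed by 1.5 on the log2 scale and 98 of 100 changed by 3, with 26 unchanged genes called. The changed genes were drawn without those of low abundance, and replicate spread followed the dispersions that the deposited errors imply. No library stood apart in the simulation, so these rates need not hold for the real libraries. Spread between libraries was measured as the SD of log2 ratios of normalized reads, with 0.5 added, over genes with a mean of at least 100. The same 0.5 was added before counting genes more than 2-fold or 4-fold apart between libraries. The remaining steps used Python 3.11.15 with scipy 1.17.1.

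The labels call the 2 libraries of a genotype biological replicates and say no more of their origin. Errors on fold changes are the authors' model errors. They rest on 2 libraries per genotype and on dispersions shared across genes.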

Results

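Fruits at anthesis were compared between CsCRC-RNAi plants and the wild-type line R1461, with 2 libraries per genotype. CRABS CLAW is known as a regulator of carpel development, and the comparison asks which transcripts differ in the fruit when CsCRC is silenced. The table listed 24317 genes, of which 3449 had a mean of 0. For those genes, a count of 0 over all libraries allows up to 0.0311 CPM, for counting error only. The mean normalized counts summed to 24100000 to the nearest 100000. With the recovered size factors this corresponds to about 25600000 and 25200000 reads on genes in the numerator libraries (size factors 1.06 and 1.05). The denominator libraries held about 23900000 and 21800000 (size factors 0.99 and 0.91).

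In the authors' deposited table, 56 genes differed between the genotypes at an adjusted p under 0.05 (DESeq2), 0.303% of the 18461 genes adjusted. Of these, 44 were lower and 12 were higher in the numerator genotype. The lower genes spanned log2 fold changes from -5.02 to -0.50, with a median of -1.63. The higher genes spanned 0.60 to 2.67, with a median of 1.77. A change of at least 2-fold was listed for 36 of the lower genes and 9 of the higher ones. A change of at least 8-fold was listed for 10 lower genes and 0 higher ones. Some of these, CsaV3_6G007550 and CsaV3_6G007580 among them, have neighbouring IDs on chromosome 6 and need not be separate changes. In several of these 10 the size of the change rests largely on 1 denominator library. Recovered normalized reads in the deeper and shallower denominator libraries were 59.4 and 300 for CsaV3_4G000280, and 153 and 32.0 for CsaV3_4G032970. They were closer, at 196 and 142, for CsaV3_1G009750. The table does not name the numerator genotype, so these directions are relative to an unnamed genotype.

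The smallest adjusted p belonged to CsaV3_5G025900, an abundant transcript with a mean normalized count of 11352. Its log2 fold change in the authors' deposited table was -1.63 ± 0.12 (SE, DESeq2 adjusted p = 9.67e-35). The mean and the fold change together place it at about 5539 normalized reads in the numerator genotype and 17165 in the denominator genotype, a 3.1-fold difference. Its reads per library were not recovered, because its mean lies above the limit of 2000. CsaV3_6G007550 was next among the lower genes, at -3.76 ± 0.41 in the authors' deposited table (SE, DESeq2 adjusted p = 6.59e-16). Its recovered reads came to 27.9 ± 9.77 normalized reads in the numerator libraries and 378 ± 139 in the denominator libraries (SD, n = 2 each).

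Among the higher genes, CsaV3_3G046020 had a log2 fold change of 1.74 ± 0.25 in the authors' deposited table (SE, DESeq2 adjusted p = 1.5e-08). It held 824 ± 71.1 normalized reads in the numerator libraries and 247 ± 70.6 in the denominator libraries (SD, n = 2 each). CsaV3_4G030710 had a log2 fold change of 1.97 ± 0.29 in the authors' deposited table (SE, DESeq2 adjusted p = 3.93e-08). It held 887 ± 291 and 227 ± 50.6 normalized reads on the same sides (SD, n = 2 each). For the 3 of these 4 genes with recovered reads, both libraries of one genotype lay above both of the other. The genes were picked by their p-values from the same libraries, so this separation adds no support. In limma on the recovered reads the fold changes of these 3 genes were -3.72, 1.77 and 1.95, and none passed the threshold (limma adjusted p = 0.789, 0.541 and 0.789).

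**Figure D1:**
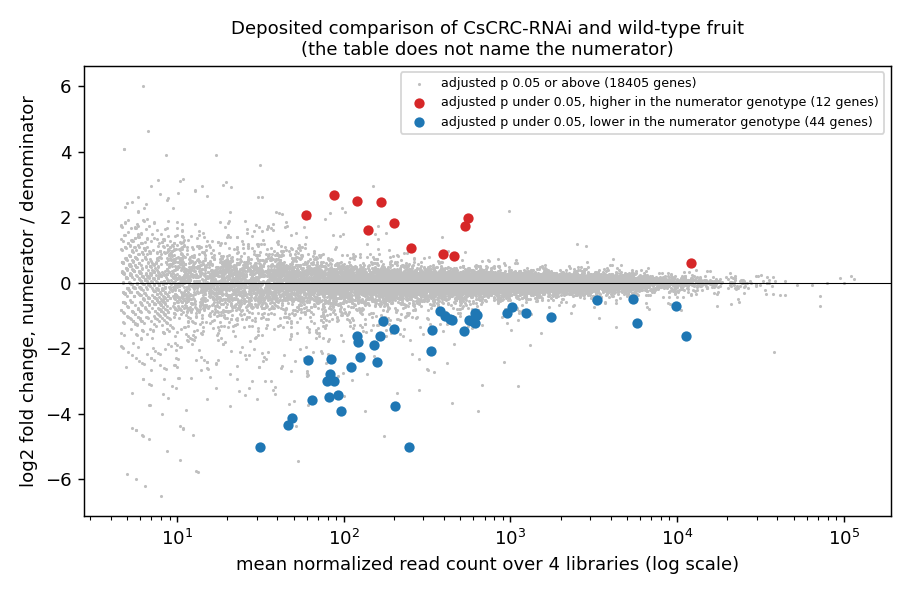
Log2 fold change of the deposited comparison (vertical axis) against the mean normalized read count over 4 libraries (horizontal axis, log scale), 1 point per gene with an adjusted p. Red points mark the 12 genes past the threshold that were higher in the numerator genotype and blue points the 44 that were lower; 10 of the blue points and 0 of the red points lie beyond a log2 change of 3.

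The called genes were of moderate abundance, with a median mean of 226 normalized reads for the higher and 224 for the lower ones, against 514 for all adjusted genes. Genes with a mean above 1000 supplied 9 of the 56 calls. The size of change that could pass depended on abundance. At the Wald statistic of the last called gene (3.79) and the median error of each class, a gene with a mean from 10 to 100 needed a 5.3-fold change. The corresponding figure was 1.83-fold for means from 100 to 1000 and 1.49-fold for means of 1000 or more. Below a mean of 10 a 37.7-fold change was needed at the median error, and 0 of 821 genes were called there (DESeq2).

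Over all 56 calls, no chromosome named in the gene IDs held more or fewer than expected after adjustment. Unplaced sequence held 4 against 0.992 expected (Fisher's exact test p = 0.0172, adjusted p = 0.207). Of the 12 higher genes, 4 carried unplaced IDs (prefix UN), against 0.213 expected from the 327 unplaced genes tested (two-sided Fisher's exact test p = 4.28e-05, Benjamini-Hochberg adjusted p = 0.00103 over 24 tests). None of the 44 lower genes did (0 genes). Chromosome 5 held 2 of the 56 calls against 7.49 expected, which did not pass (Fisher's exact test p = 0.0286, adjusted p = 0.228). Of the 4 higher unplaced genes, 2 had adjacent IDs, while Fisher's exact test counts every gene as independent, so its p may be too small. Whether unplaced genes share reads with near-identical copies was not tested, so their counts are uncertain.

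Reads per library were recovered for 49 of the 56 called genes, 39 lower and 10 higher. In 39 of the 39 lower genes both denominator libraries lay above both numerator libraries, and in 10 of the 10 higher genes both numerator libraries lay above both others. Chance alone would separate the genotypes in 33.3% of unchanged genes, and these genes had been selected by the test. In the lower genes, the shallower denominator library was above the deeper one in 31 of 39, and more than 2-fold above it in 11, while the opposite 2-fold difference occurred in 1. The numerator libraries were also more than 2-fold apart in 8 of these 39 genes, with the deeper one above in 5 and the shallower one above in 3. These 2-fold counts were taken with 0.5 added to each normalized value.

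**Figure D2:**
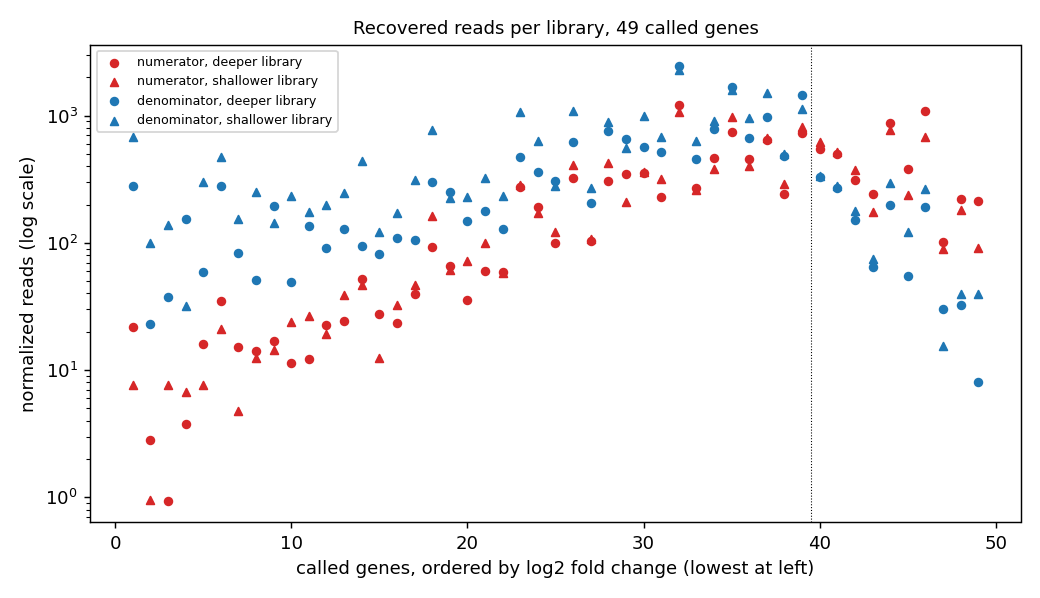
Normalized reads per library (vertical axis, log scale) for the 49 called genes with recovered reads, ordered along the horizontal axis by log2 fold change; circles are the deeper and triangles the shallower library of the numerator (red) and denominator (blue) genotype. The dotted line parts the 39 lower from the 10 higher genes, and at the left the blue triangles are often well above the blue circles.

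The spread between genotypes overlapped the spread between libraries of one genotype. Over 11097 genes with a mean of at least 100, the SD of log2 ratios was 0.33 between the numerator libraries and 0.38 between the denominator libraries. Across genotypes it was 0.32 and 0.34 for the pairs with the deeper denominator library, and 0.37 and 0.42 for those with the shallower one. Denominator libraries differed by more than 2-fold in 2.49% of these genes and numerator libraries in 1.41%.

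**Figure D3:**
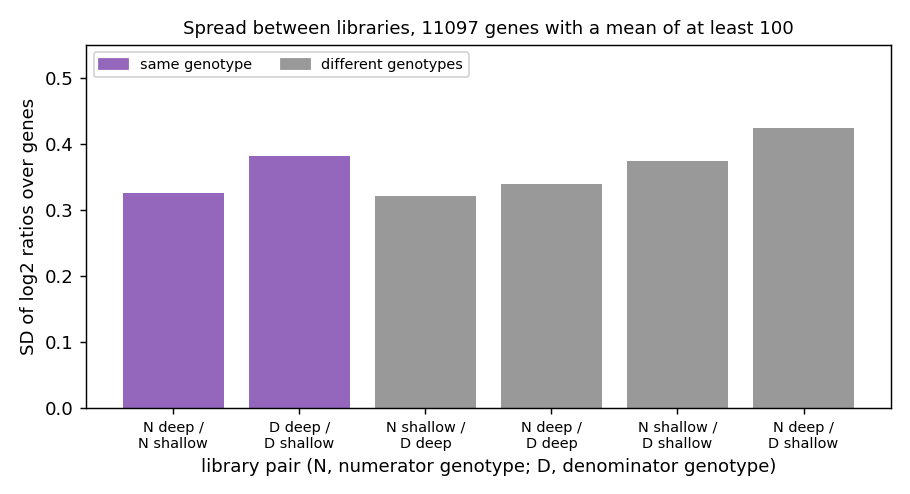
SD of log2 ratios of normalized reads (vertical axis) over 11097 genes for each pair of the 4 libraries, with pairs of the same genotype in purple and pairs of different genotypes in grey. The smallest bar, 0.32, is a pair of different genotypes, and the largest, 0.42, contains the shallower denominator library.

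The unadjusted p-values of the deposited table gave 772 genes under 0.05, 535 lower and 237 higher. Chance alone would give 1043 of the 20868 tested. Among the 18461 genes with an adjusted p the shortfall was smaller, 766 genes against 923 by chance. Limma on the recovered reads called 0 of 15254 genes, with 722 at an unadjusted p under 0.05. Of the 49 called genes with reads, 47 were among those 722.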

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

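Of the alternatives here, only the 2-fold limit and the threshold of 0.01 were planned; the others were chosen after seeing the data. The deposited count of 56 genes stayed within 1.5 times under most settings that re-used the deposited test results, which are not independent of it. It was 45 with a 2-fold limit, 74 at an adjusted p under 0.10, and 51 when every gene with a p was adjusted. It was 57 and 42 for means of at least 10 and 100, and 55 after centring fold changes on genes of mean 1000 or more, a shift of 0.0003. At an adjusted p under 0.01 the count was 29. An empirical null, which divides the Wald statistic by its robust SD of 0.817, gave 194 genes including all of the 56. The cause of that narrow spread was not tested beyond the tests given further on. Between 76.2% and 82.8% of calls were lower in the numerator genotype under these settings. Of the 56 called genes, 7 had no recovered reads, CsaV3_5G025900 among them, and were not tested in limma. Limma voom on the recovered reads gave 0 genes, and so 0 of the other 49. Without 1 library it gave between 0 and 83. The count was 83 without the deeper denominator library (81 of them lower, and 23 of the 83 among the 49 called genes), 21 without the shallower one (5 of them among the 49), and 0 without either numerator library. With 1 library left on a side, that library is assumed to vary like the pair on the other side. The named genes passed under each alternative that used the deposited p-values. They had been chosen for the smallest of those p-values, so this outcome followed from the choice. In limma, 4 of 15 values passed, and CsaV3_4G030710 passed in 0 of its 5 fits. No paired analysis was possible because the deposited columns carry no replicate numbers and the recovered libraries were not matched to the labelled replicates. The planned edgeR and DESeq2 fits, with their normalization and filter alternatives, were not run. The table has no count column, and the recovered reads were tested with limma alone. The camera and fry tests were not run because no list was matched to the IDs. Depth and the 2 libraries per genotype limit the 821 tested genes with a mean below 10, where a change of 37.7-fold was needed at the median error.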

Other observations

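The test of neighbouring positions by chance, the values without unplaced genes, the medians by abundance and the counts of genes apart in a single library were chosen after the result was seen, and limma was added after the files were seen, though its comparison of splits was fixed before it was run. Some genes of mean 100 or more stood apart in a single library. The deeper denominator library had 10 genes more than 4-fold above each of the other libraries and the shallower one 7, against 0 in either numerator library. More than 4-fold below each of the others were 3 genes in each denominator library, and 3 and 1 in the deeper and shallower numerator libraries. Of the 17 genes above the others, 1 was called. Of the uncalled genes of that abundance, which can include some of these 17, 21 had at least a 4-fold change in the deposited table, 18 of them lower in the numerator genotype, and 8 had their highest value in the shallower denominator library.

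Some called genes lay close together, among them 5 of the 11 on chromosome 6. In ID order, 7 of the 56 had another called gene within 5 places, in 3 runs: 3 lower genes within 5 listed places and 2 lower genes within 3 places, both on chromosome 6, and 2 adjacent higher genes on unplaced sequence. The run of 3 held CsaV3_6G007540, CsaV3_6G007550 and CsaV3_6G007580, with deposited log2 fold changes of -3.58, -3.76 and -5.02. The run of 2 lower genes held CsaV3_6G039690 and CsaV3_6G039710, at -2.43 and -5.01. Several genes lower by at least 8-fold thus lie in these runs. Of 100000 random placements a share of 0.0039 reached 7, and for the 5 placed genes alone the share was 0.019. At 5 places this is below the bound of 5% set for chance, but that distance was chosen after the runs were seen. At 1, 2 and 10 places the share was 0.0072, 0.0027 and 0.00915, and at 20 and 50 places it was 0.0789 and 0.376, so the outcome depends on the distance and does not exclude chance. The uncalled genes within 10 places of the runs also had larger Wald statistics than elsewhere. Their mean absolute value was 0.995, against a median of 0.679 over all shifts along the gene order (percentile 99.6). Without unplaced genes, whose IDs follow no chromosome, the gap was smaller, at 0.869 against 0.676 (percentile 97.8). A candidate explanation is a stretch in which many genes differ between the plants, such as a segment that varies in sequence. These neighbours had no common direction, with 52.5% of all 61 lower and 25 of the 41 placed ones lower. Of the 41, 4 had an unadjusted p under 0.05. Co-regulated gene copies and reads shared between copies stay open, because no sequence was used here.

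The deposited p-values were skewed toward 1, with a median of 0.605. Genes with few reads do not account for this as the whole cause, since the median was still 0.571 among genes with a mean of at least 100. The skew was smaller in abundant genes, with a median of 0.589 for means from 100 to 1000 and 0.546 for means of 1000 or more, so few reads stay open as part of the cause. A hidden division of the libraries that crosses the genotypes might inflate the error. In limma the other splits of the libraries gave at most 1 gene, against 0 for the real split, which is too few to decide. At an unadjusted p under 0.05, the deeper library of each genotype against the shallower one gave 806 genes. The remaining split gave 387, against 722 for the real split, so the real split did not stand above both. Chance alone would give a share of 0.05 of the 15254 genes tested, which is more than 722 and fewer than 806. The authors' estimate of dispersion from 2 libraries per genotype remains open and was not tested.

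The shallower denominator library may stand apart from the others over all genes, which would bear on the excess it shows in the lower genes. The SD of log2 ratios in the denominator pair was 1.18 times that of the numerator pair, between the bounds set for this test, so it was not decided. Each of the 3 pairs that include this library (0.37, 0.38 and 0.42) was wider than each of the others (0.32, 0.33 and 0.34). With 1 library, a difference between fruits or plants and a difference in handling cannot be told apart.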
